A study of Mus musculus with 4 samples.

How the data were processed

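RNA of the dentate gyrus, the part of the hippocampus that holds the granule cells, was measured on Affymetrix exon-type arrays in 4 samples from wild-type C57/Black6 male mice of 8 weeks. Per the labels, 2 samples were taken 4 h after electroconvulsive stimulation (ECS) and 2 samples 4 h after a sham treatment. ECS is a brief current across the head that evokes a generalised seizure. The labels call the 2 samples of each group biological replicates and do not say whether a sample holds tissue of 1 mouse or of several, so p-values of the gene test measure the spread between these samples. Per the labels' protocols, ribosomal RNA was depleted and sense-strand DNA was made with random primers, labelled with biotin and hybridised.

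The deposited values are log2 values per probeset, a group of probes that mostly covers 1 exon. Per the submitters' processing notes the tools were oligo and RMA, and versions were not given in the sources used here. RMA corrects the background of each array, normalizes between arrays and summarises the probes of a probeset, which compresses differences of dim probesets and removes differences in total signal between arrays. Each array had 631652 probesets, with a median log2 value between 5.97 and 6.03. A deposited table, whose other numeric columns (unit other) count the exons and probesets of each RefSeq transcript, pairs transcripts and gene symbols with probesets. Its genome build was not given in the sources used here. The start and end positions printed were taken from this table, with starts counted from 1. Of 24666 coding transcripts, 24385 had a coding length that is a multiple of 3 when its positions were read as starting from 0.

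Symbols were updated through the RefSeq accession with a gene table of assembly GRCm38.p6, from which no position was taken. Of 25635 distinct transcripts, 24932 matched, and the others took the updated symbol of another transcript with the same deposited symbol, where there was 1, or kept the deposited symbol. The table placed 229712 probesets (36.4%), 225690 of them in 1 gene and 4022 in several genes, and 401940 probesets were not placed. Of the 2885 table entries of transcripts with 1 exon, 2833 had no probeset, so intronless genes such as Junb were not measured here. A gene value is the mean of the log2 values of the probesets placed in that gene alone, in each sample. This gave 17425 genes with a median of 10 probesets, and all were tested. Another deposited table has 4 columns of per-sample values named E0H and E4H, each as A and B. The labels give no 0 h point, so these columns match no label and were not used. Whether the E0H columns hold the sham samples is not known, and if they do, their name leaves the interval after sham treatment in doubt.

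Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided, no block), with Benjamini-Hochberg adjustment and a threshold of 0.05. Changes are means of the 2 ECS samples minus means of the 2 sham samples on the log2 scale, with the standard error (SE) of the moderated fit. The fit had 2 residual degrees of freedom and borrowed 3.18 from all genes. For 2 samples against 2, an exact permutation test cannot give a p below 0.333, so every p-value rests on the spread shared across genes. The small number of arrays limits the precision.

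32 gene lists with at least 5 measured members were fixed before the data were examined and tested with limma's camera at its preset correlation of 0.01, adjusted over the lists. An estimated correlation and fry were alternatives. At the preset, camera treats genes as nearly independent, so its p-value counts genes more than the 4 samples. The fry test asks whether the members of a list move on balance in 1 direction and does not compare them with other genes. Unequal change along a transcript was tested with limma's diffSplice (F test) on bright probesets, those with a mean log2 value of at least 5.96, the median of all probesets on the array, in genes with at least 4 of them. This left 168271 probesets. The test pools the spread of all probesets of a gene as if they were independent, so a small p reflects many probesets and not more samples. The median of the probesets in the gene table alone had at first been used for this filter, against the plan, and its results were seen before the fixed filter was restored. It is kept as an alternative that was added after the data were examined. Named are the 15 largest rises and the 10 largest falls among genes past the threshold whose groups do not overlap, a fixed set of activity, DNA methylation and growth factor genes, up to 4 members of each list with the smallest p, and the 6 genes with the smallest p in the transcript test with Homer1, Bdnf and Arc. Genes named outside this rule are said to be so.

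The tests were tried on simulated data with the spread of the real arrays. Among 17425 simulated genes, 200 of them changed, the gene test found 1.49% of the changes of 0.5 on the log2 scale, 66.0% of those of 1 and 94.8% of those of 2, with 2.8 false calls per run over 5 runs. With eBayes set to follow the mean, it found 19.7%, 78.5% and 98.2%, with 5.8 false calls. A list of 30 genes shifted by 0.3 was found by camera in 100% of 20 runs, and an unshifted list in 0%, in data simulated without correlation between genes. For the transcript test on 11958 genes, noise was also drawn without correlation between probesets, so real error rates may differ. The outcome depended on the spread of the probesets. With 1 spread for all probesets of a gene, 4.05% of its calls were false when 200 genes had 1 changed probeset, it found 33.0% of the changes of 1 and 85.6% of those of 2, and 0.4 genes were called per run when none changed. With a separate spread for each probeset, 68.1% of its calls were false, it found 24.6% and 88.6%, and 201.8 genes were called per run when none changed. That is more than were called in the real data, and the share of false calls among the real ones is not known.

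Alternatives covered the gene summary, probesets of several genes, normalization between arrays, filters on low values, the replicate number as a block, each sample left out, the variance model, the threshold and the set test. Figures were drawn with matplotlib 3.10.9.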

Results

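Gene expression in the microdissected dentate gyrus of mice was compared 4 h after ECS and, per the labels, 4 h after sham treatment, with 2 samples in each group. The arrays were alike in brightness, with median log2 values of 5.98 and 6.03 in the sham samples and 6.01 and 5.97 in the ECS samples. Across genes, which are not independent replicates, Pearson's r was 0.993 between the 2 sham samples, 0.993 between the 2 ECS samples and 0.987 to 0.990 between groups. Across probesets r was 0.9737 and 0.9738 within the groups and 0.9694 to 0.9735 between groups, highest for sham replicate 2 with ECS replicate 1. The replicate difference had an SD over genes of 0.23 on the log2 scale in each group.

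The comparison asked which genes differ after the stimulation. At 4 h, genes of the response to neuronal activity were among the strongest rises, and the granule cell markers Tdo2 and Dsp were among the strongest falls. Arl4d, a small GTPase, rose 6.77-fold, from 6.33 ± 0.20 in sham to 9.09 ± 0.08 after ECS (log2, SD, n = 2). Inhba, which encodes an activin subunit, rose 4.90-fold, Gadd45b, a stress and activity gene linked to DNA demethylation, rose by 2.19 ± 0.09 on the log2 scale (SE), and the transcription factor Atf3 rose by 2.10 ± 0.13. Tdo2, a tryptophan-degrading enzyme found in granule cells, fell 7.25-fold, from 7.54 ± 0.21 to 4.69 ± 0.11 (log2, SD, n = 2). The ECS mean of Tdo2, like the dimmer group mean of Atf3, Cenpa, Gmnc, 5330413P13Rik and Lpar4, lay below 5.96, the median of all probesets, where RMA compresses differences and a fold can be understated.

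Of 17425 genes tested with limma, 121 passed an adjusted p of 0.05, of which 87 were higher and 34 lower after ECS. Folds among the higher genes ran from 1.63 to 6.77 with a median of 2.14, and 52 exceeded 2-fold. Among the lower genes they ran from 1.65 to 7.25 with a median of 1.92, and 12 exceeded 2-fold. In all 121 genes both ECS samples lay beyond both sham samples. Such separation was seen in 49.7% of all genes, against 33.3% by chance. The smallest adjusted p was 0.0135 and 2986 genes had an unadjusted p under 0.05, 1101 higher and 1885 lower. The median change over all genes was -0.04.

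The other large rises were in Nptx2, a secreted pentraxin of excitatory synapses (2.06 ± 0.14 on the log2 scale, SE), Cenpa, the centromeric histone (1.90 ± 0.12), Tll1, a secreted metalloprotease (1.82 ± 0.09), and Klf10, a transcription factor (1.81 ± 0.09). Dusp14 rose by 1.70, the kinase gene Pim1 by 1.68, Samd4 by 1.64, the transcription factor Egr3 by 1.58, Etv3 by 1.58, Pmepa1, a regulator of TGF-beta signalling, by 1.57, and Stk40 by 1.54. Dusp14 and Egr3 were each measured by 1 probeset. After Tdo2, the largest falls were in Gmnc, a regulator of multiciliated cells (-1.81 ± 0.17), and Stc1, a secreted glycoprotein (-1.53 ± 0.12). The non-coding transcript 5330413P13Rik fell by 1.48, the desmosomal gene Dsp by 1.37, Kif26b by 1.36, the protocadherin Fat4 by 1.20, Igfbp5, which binds insulin-like growth factors, by 1.17, Glt8d2 by 1.13 and the receptor gene Lpar4 by 1.13. Adjusted p over these 25 genes lay between 0.0135 and 0.0395. The count of 121 rested on all 4 samples, since it was 2 without sham replicate 1, 0 without sham replicate 2, 0 without ECS replicate 1 and 5 without ECS replicate 2. It was 0 by the same limma test when the median of a gene's probesets replaced the mean (2403 at an unadjusted p under 0.05), and 750, including all 121, when the variance was allowed to follow the mean, with 383 higher and 367 lower.

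**Figure D1:**
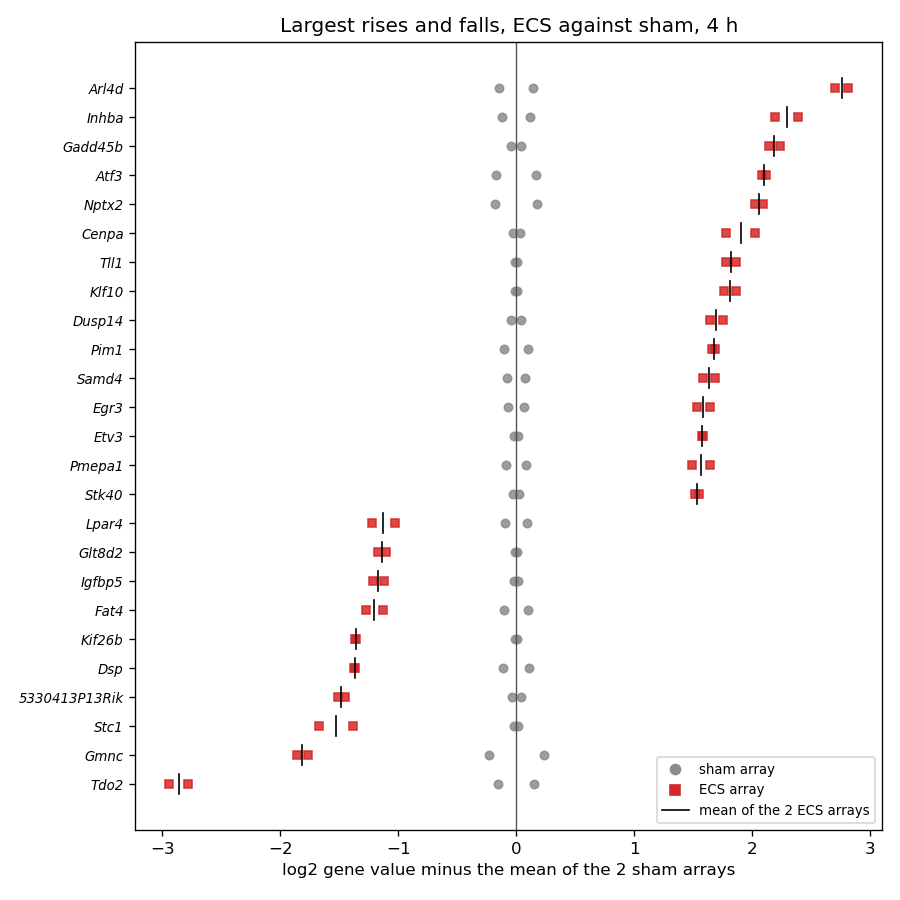
Log2 gene value of each array minus the mean of the 2 sham arrays (horizontal axis) for the 15 largest rises and 10 largest falls (vertical axis), with sham arrays as grey circles, ECS arrays as red squares and the ECS mean as a black line. The ECS means range from 2.76 for Arl4d to -2.86 for Tdo2, and both ECS arrays lie beyond both sham arrays in each gene.

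Genes that neurons induce with activity formed the clearest group. Of 40 synaptic, secreted and signalling effectors, 12 rose and 0 fell over all genes tested, and 27 rose and 1 fell adjusted over the list alone, with a median change of 0.62. Besides Gadd45b, Inhba, Pim1 and Nptx2, the 12 included Arc, which organises the trafficking of AMPA receptors (1.38 ± 0.09 on the log2 scale, SE), and Homer1, a postsynaptic scaffold gene (0.83 ± 0.09). The Homer1 value averages probesets that changed unequally. The list was shifted upward by limma's camera (adjusted p = 4.82e-26) and by fry (adjusted p = 0.0116), but not past the threshold by camera (adjusted p = 0.364 with an estimated correlation). Of 28 activity-dependent transcription factors, 5 rose over all genes tested, namely Klf10, Egr3, Atf3, Csrnp1 (0.93) and Fosl2 (1.17, named although outside the rule), and 9 adjusted over the list alone. This list had a median of 0.25 and a camera adjusted p of 4.68e-08 (adjusted p = 0.364 with an estimated correlation). The immediate early genes Fosb, Fos, Egr1 and Npas4 did not pass over all genes tested. Fosb differed by 1.18 (adjusted p = 0.0619), Fos by 0.76 (adjusted p = 0.139), Egr1 by 0.53 (adjusted p = 0.0924) and Npas4 by 0.36 (adjusted p = 0.328). Of 16 feedback inhibitors of MAP kinase signalling, Dusp14 alone rose over all genes tested and 4 adjusted over the list alone, the others being Dusp5 (0.76), Dusp4 (0.73) and Spred2 (0.57). The camera adjusted p was 4.19e-04 (adjusted p = 0.789 with an estimated correlation), and Dusp1 differed by 0.20. Genes induced by glucocorticoids had a median of 0.20 over 21 members and a camera adjusted p of 7.31e-05 (adjusted p = 0.872 with an estimated correlation). None of the 21 passed over all genes tested and 3 rose adjusted over the list alone, which were Cdkn1a (1.09), Klf9 (0.51) and Mt2 (0.67). Some of the 21, among them Cdkn1a and Dusp1, also belong to the activity or MAP kinase lists, so this shift is not independent of theirs.

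Of 32 genes of DNA methylation and demethylation, 2 rose over all genes tested, Gadd45b and Tet3, an enzyme that oxidises methylcytosine (0.86 ± 0.09, adjusted p = 0.0395). Adjusted over the list alone, 5 rose and 3 fell. Tet2 differed by 0.55 (adjusted p = 0.103), Tet1 by -0.18, the methyltransferase genes Dnmt1 by -0.35 (adjusted p = 0.165), Dnmt3a by 0.29 and Dnmt3b by -0.16, Gadd45g by 0.37, Mbd2 by 0.64 and the repair enzyme Ogg1 by -0.57. The list median was -0.02 and its mean 0.09. Camera did not call the list (adjusted p = 0.331), while fry placed it upward (adjusted p = 0.0116). Of 46 growth factor genes, among them Fgf12, Fgf13 and Fgf14, whose products stay inside the cell (named although outside the rule), Inhba rose and the neurotrophin Ntf3 fell (-0.93 ± 0.10, adjusted p = 0.0395) over all genes tested, and 5 rose and 3 fell adjusted over the list alone. The list does not hold every growth factor gene. Pdgfc, outside the list and the rule, rose by 1.46 ± 0.10 (adjusted p = 0.0162 by limma). Bdnf, a neurotrophin, differed by 0.81 ± 0.13 (adjusted p = 0.0902), Vegfa by 0.59 (adjusted p = 0.0767), Tgfb3 by 0.68, Pdgfb by 0.80 and Fgf2 by 0.22 (adjusted p = 0.345). Among 27 neuropeptide and granin precursors 0 passed over all genes tested by limma, and 5 rose and 2 fell adjusted over the list alone, with Vgf at 0.75, Chga at 0.68, Chgb at 0.47, Penk at -0.56 and Npy at 0.32.

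Voltage-gated sodium and calcium channel genes had a median of -0.15 over 29 members and a camera adjusted p of 0.0431 (adjusted p = 0.918 with an estimated correlation). The sodium channel gene Scn9a fell by 0.90 over all genes tested, and 4 fell adjusted over the list alone, with Scn3b at -0.60, Scn3a at -0.51 and Cacna1d at -0.49. This list was not called without sham replicate 1 (adjusted p = 0.294), without ECS replicate 2 (adjusted p = 0.187), with the median of probesets (adjusted p = 0.0798), in the upper 50% of genes by mean (adjusted p = 0.143) or with dim probesets left out (adjusted p = 0.0812). Glutamate receptor genes had 0 of 25 members past the threshold by limma over all genes tested and 0 adjusted over the list alone, with a median of -0.08, and fry placed the list downward (adjusted p = 0.0116) where camera did not (adjusted p = 0.248). Grik3 differed by -0.67. Among 17 GABA receptor genes, Gabrd, the delta subunit of extrasynaptic receptors, fell by 0.83 over all genes tested, and adjusted over the list alone Gabra4 (0.60) rose and Gabrd fell. Among 53 potassium channel genes 0 passed over all genes tested by limma and Kcnk1 (0.69) rose adjusted over the list alone. Camera adjusted p was 0.936 for GABA receptors and 0.907 for potassium channels. The median and mean of the GABA receptor list were 0.01 and -0.03, with camera upward and fry downward.

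Of 19 circadian clock genes, Cry1, a repressor of the clock (0.98 ± 0.11), and Bhlhe41, another repressor (1.47 ± 0.17), rose over all genes tested. Adjusted over the list alone, 5 rose and 8 fell, among them the output activator Hlf (-0.89) and Per3 (-0.80), and camera found no shift of the list as a whole (adjusted p = 0.917). Of 34 cell cycle genes, the replication helicase gene Mcm6 fell by 0.96 over all genes tested and 2 fell adjusted over the list alone, the other being Tyms (-0.74), with a camera adjusted p of 0.297. Of 33 heat shock and endoplasmic reticulum stress genes, Dnajb5 rose by 1.25 over all genes tested, and 2 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.833). Sv2c, a synaptic vesicle protein that is also a marker of mossy cells, rose by 0.71 and was the 1 of 37 vesicle genes past the threshold over all genes tested and adjusted over the list alone (camera adjusted p = 0.662). Homer1 was the 1 of 26 postsynaptic scaffold genes past it in both counts (camera adjusted p = 0.147). Its gene value averages 6 probesets shared with a short transcript, higher by 1.72, and 9 of the long transcripts alone, higher by 0.23. The rise therefore lay mostly outside the part found in the long transcripts alone. Of 22 genes of neural progenitors and immature neurons 0 passed over all genes tested by limma, and adjusted over the list alone Hes1 (0.72) rose and Tbr1 (-0.78) fell, with a camera adjusted p of 0.924. No member passed over all genes tested or adjusted over the list alone in the lists of inflammation (28 genes, camera adjusted p = 0.917), glycolysis (23 genes, adjusted p = 0.297) and cholesterol synthesis (26 genes, adjusted p = 0.870).

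**Figure D2:**
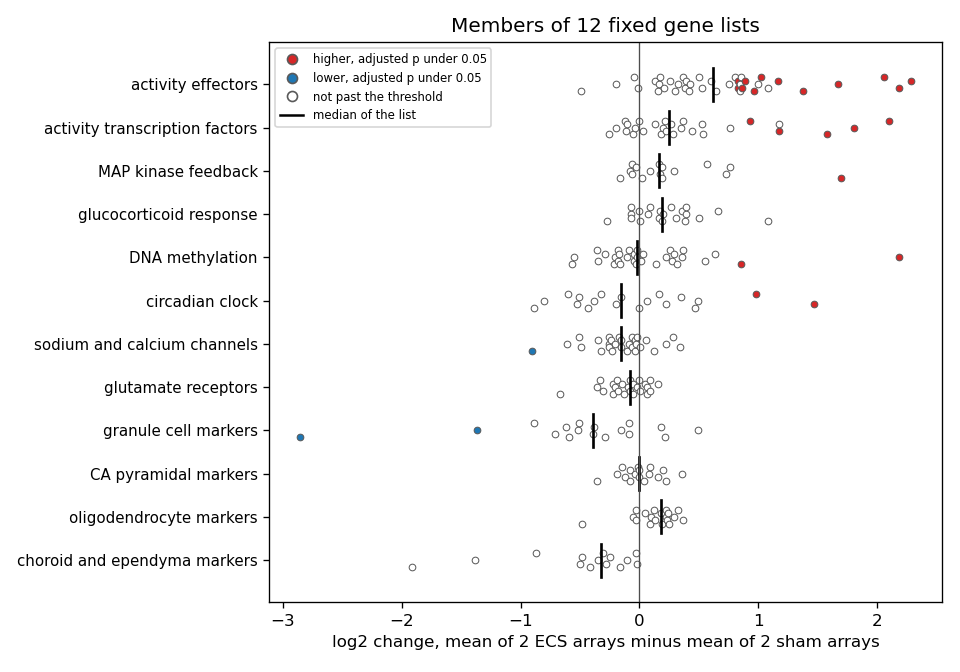
Log2 change, mean of the 2 ECS arrays minus mean of the 2 sham arrays (horizontal axis), of each measured member of 12 fixed gene lists (vertical axis). Red and blue circles are genes past an adjusted p of 0.05 over all genes, open circles are the others, and black lines are list medians. The medians run from 0.62 for activity effectors to -0.39 for granule cell markers.

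Markers of dentate granule cells had the median farthest from 0 among the cell type lists, while their mean and that of the choroid plexus and ependymal markers were both -0.50. Of 17 measured markers, Tdo2 and Dsp fell over all genes tested, and 9 fell and 0 rose adjusted over the list alone, with a median of -0.39 and a camera adjusted p of 4.74e-05 (adjusted p = 0.789 with an estimated correlation). The neuropeptide receptor gene Npy1r differed by -0.89 (adjusted p = 0.0591) and Lct by -0.62, while Prox1, the transcription factor that defines granule cells, differed by 0.22 ± 0.09 (adjusted p = 0.318). Of the other neurons, 17 markers of CA pyramidal cells had a median of 0.00 (camera adjusted p = 0.801), 11 of mossy cells -0.05 (adjusted p = 0.748) and 17 of interneurons 0.02 (adjusted p = 0.870). Sv2c rose among the mossy cell markers over all genes tested, and 2 rose adjusted over the list alone, the other being Cda (0.39). For mossy cells the median was below 0 while the mean (0.04) and the test pointed upward.

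Markers of other cells differed between single samples. Choroid plexus genes were high in sham replicate 2, where transthyretin (Ttr, named although outside the rule) stood at 10.16 against 6.12 in sham replicate 1 and 6.55 and 5.90 after ECS, and Clic6 at 7.15 against 4.75, 4.88 and 4.25. The 14 choroid plexus and ependymal markers were all lower after ECS, with a median change of -0.33 (camera adjusted p = 0.10). Oligodendrocyte markers had a median of 0.18 over 19 genes and a camera adjusted p of 0.0431 (adjusted p = 0.918 with an estimated correlation). Their median deviation from the mean of the 4 arrays was 0.39 in ECS replicate 1 and -0.18 in ECS replicate 2, and without ECS replicate 1 their mean change turned to -0.13. The call was also lost without either sham replicate (adjusted p = 0.0512 and 0.215), with array medians set equal (0.0681), after quantile normalization (0.0676), in the upper 50% of genes by mean (0.137) and with dim probesets left out (0.0812). Blood cell markers had a median of 0.23 over 8 genes and a camera adjusted p of 0.0266 (adjusted p = 0.789 with an estimated correlation), which ended without sham replicate 2 (adjusted p = 0.225) or ECS replicate 2 (adjusted p = 0.0546) and with dim probesets left out (adjusted p = 0.0751). The medians were -0.01 for astrocytes (19 genes, camera adjusted p = 0.976), -0.07 for oligodendrocyte progenitors (9 genes, adjusted p = 0.917), -0.02 for microglia (16 genes, adjusted p = 0.976), -0.03 for endothelial cells (19 genes, adjusted p = 0.807) and -0.03 for mural cells and fibroblasts (17 genes, adjusted p = 0.924). No member of these 5 lists, nor of the choroid plexus, oligodendrocyte, blood, CA pyramidal and interneuron lists, passed over all genes tested or adjusted over the list alone.

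Because the array measures single exons, change along each transcript was compared as well. Syne1 and Homer1 showed change that differed between probesets of different annotated transcripts. In Syne1, which encodes a large spectrin-repeat protein of the nuclear envelope, 34 of 35 bright probesets of NM_153399 (chromosome 10, 4795849 to 5009592) were higher after ECS, by 0.68 on average. The 39 bright probesets of NM_001079686 alone (5151834 to 5326342) averaged -0.25 and the 21 shared by NM_001079686 and NM_022027 averaged -0.21 (diffSplice adjusted p = 5.07e-50). NM_153399 does not overlap these transcripts and shares no tested probeset with them. As a whole gene, Syne1 differed by 0.10, and by -0.21 with the median of its probesets. Homer1 lies on chromosome 13 (94074450 to 94174917), and its short transcript NM_011982 ends at 94126785. The 6 probesets shared with the short transcript were higher by 1.72 on average (0.93 to 3.01), while the 8 bright probesets found in the long transcripts NM_147176 and NM_152134 alone were higher by 0.17 (0.04 to 0.36), with a diffSplice adjusted p of 1.50e-11. Within the 6, changes of 3.01 and 2.92 stood apart from the others, at 0.93 to 1.21.

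Of 11958 genes with at least 4 bright probesets, diffSplice called 72, and 857 had an unadjusted p under 0.05. Of these 72, 27 were also called as whole genes. Adgrb1, an adhesion receptor (adjusted p = 2.52e-14), Ptprz1, a receptor phosphatase (7.03e-09), and Arc (adjusted p = 0.00373) each had 1 annotated transcript, and 36 of 39, 34 of 37 and 4 of 4 of their bright probesets were higher. Capn3, a calcium-dependent protease (chromosome 2, 120289329 to 120330649, adjusted p = 7.75e-08), and Tiam2, an activator of Rac (chromosome 17, 3326573 to 3519397, adjusted p = 7.90e-08), each had 2 annotated transcripts that share all their probesets, so these could not be told apart. In Capn3 2 of 16 bright probesets were higher, with changes from -2.28 to 0.17, and in Tiam2 3 of 23, with changes from -1.94 to 0.26. As whole genes Tiam2 fell by 0.84 and Capn3 differed by -0.90 (adjusted p = 0.0523). Bdnf had 3 bright probesets, too few for the test, and these were higher by 0.73 to 1.22. The count of 72 was 20 without sham replicate 1, 49 without sham replicate 2, 87 without ECS replicate 1 and 18 without ECS replicate 2, of which 19, 26, 20 and 12 were among the 72, and Arc was called in none of these (adjusted p between 0.0508 and 0.226) and Ptprz1 was not called without ECS replicate 2 (adjusted p = 0.114). Sham replicate 1 with ECS replicate 2 against the other 2 samples gave 39 calls, and data simulated without any change gave 0.4 calls per run with 1 spread for all probesets of a gene and 201.8 with a separate spread for each, so the share of false calls among the 72 is unknown.

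**Figure D3:**
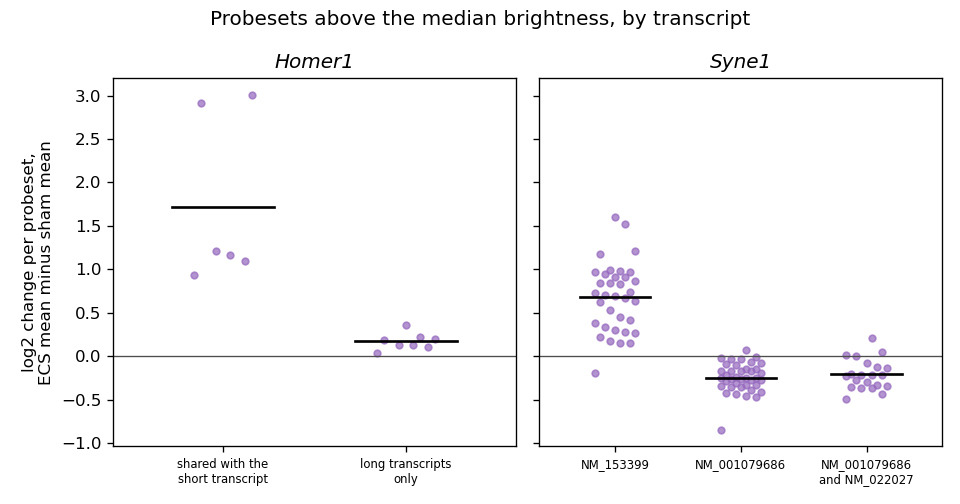
Log2 change of each bright probeset (vertical axis, mean of 2 ECS arrays minus mean of 2 sham arrays), grouped by the transcripts that hold it (horizontal axis), for Homer1 and Syne1, with black lines at class means. The Homer1 classes average 1.72 and 0.17, and the Syne1 classes 0.68, -0.25 and -0.21.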

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

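All tests of an explanation in this part were chosen only after the result was seen.

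Probesets that the deposited gene table does not place were not used in the comparisons. Of 401940 such probesets, 3158 had a brighter group mean of at least 5.96 on the log2 scale and differed at least 2-fold between groups with the ECS samples beyond the sham samples, 1706 higher and 1452 lower, against 1080 and 2234 in the other 2 ways of splitting the 4 samples into pairs. By limma, 0 of all 401940 passed an adjusted p of 0.05, and 25040 had an unadjusted p under 0.05. Single probesets in the gene table gave 0 of 229712 as well, with 23377 under 0.05.

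Granule cell markers had a median change of -0.39, with 14 of 17 lower after ECS, 2 of them called over all genes tested, and a camera call that was lost (adjusted p = 0.789 with an estimated correlation). A smaller share of granule cells in the ECS dissections would lower them alike only if each were found in granule cells alone, which was not measured. Of 17 markers, 9 lay more than 2 SE from the list median, with Tdo2 at -2.86 and Prox1 at 0.22. Markers shared with other cells would also fall unequally, so this test cannot decide. Choroid plexus tissue in sham replicate 2 was also weighed, since 9 of 9 choroid plexus genes were higher there, by a median of 0.95. Against sham replicate 1 alone the granule cell median was still -0.37, so this tissue does not account for the lower median. An effect of the stimulation on granule cell expression stays open as a hypothesis, and so does a smaller share of granule cells.

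Clock genes moved both ways, 5 higher and 8 lower of 19 adjusted over the list alone. Of 11 sorted by phase, Nr1d1, Nr1d2, Dbp, Tef, Hlf, Per3 and Ciart were lower and Arntl, Npas2, Clock and Cry1 higher, and all 11 lay on the side that a shift of phase predicts. This sorting was made after the values were seen, so it is no evidence for such a shift. Of the 8 clock genes left out of it, 5 were higher, among them Per2 (0.50) and Bhlhe41 (1.47), and 3 were lower, among them Rorb (-0.38). Besides Cry1, Bhlhe41, Hlf and Per3, the clock genes in this paragraph are named although outside the rule. A different time of day at dissection and a change of the clock by the stimulation cannot be told apart, because the labels give no time of day, and unused columns named E0H leave the interval after sham in doubt.

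Unequal change along a transcript may come from probesets that respond unevenly because they are dim or saturated. For Syne1 the share of higher probesets differed by 88.8 percentage points between NM_153399 (34 of 35) and the other transcripts (5 of 60). Their sham brightness overlapped (6.66 to 12.48 and 6.81 to 11.61), and uneven response to 1 change would not be expected to turn the sign. In Adgrb1, with 1 annotated transcript, 36 of 39 were higher, so a few probesets turned it there. The Syne1 values argue against uneven response as the whole cause but do not exclude it. For Homer1, both classes cover a common range of sham brightness. Within it, the lowest change of 3 shared probesets exceeded the highest of 7 long-only probesets by 0.99 on the log2 scale. Brightness therefore does not account for the difference between the classes there. Among all shared probesets changes ran from 0.93 to 3.01, with the largest at low sham brightness, and the annotated transcripts do not explain that spread. For the other genes also called as a whole the question stays open, because in 17 of 26 all tested probesets moved the same way and differed in size alone. An altered choice of transcript after ECS stays a hypothesis for Homer1. In Syne1 the classes lie in regions that do not overlap, so separate changes of separate transcripts are as open as an altered choice.

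The 4 samples can be split into pairs in 3 ways, too few for a share under 0.05. The real split was the 1 split with as many calls, with 121 genes against at most 0 in the others by limma (725 at an unadjusted p under 0.05), and the 1 split with as many calls of unequal change, with 72 against at most 39. Each other split puts ECS and sham samples in both groups, so an effect of ECS would widen its spread and lower its calls. These counts therefore do not show what the real split would give without an effect.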

How the results depend on the processing

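The crossed pairing blocks sham replicate 1 with ECS replicate 2 and sham replicate 2 with ECS replicate 1. This pairing and the brighter filter, which leaves out probesets below the median of the probesets in the gene table, were added after the data were examined. The 121 called genes became 125 with probesets of several genes kept, 116 with array medians set equal, 115 after quantile normalization and 164 with dim probesets left out. By limma the count was 0 with the median of probesets (2403 at an unadjusted p under 0.05), 989 in the upper 50% of genes by mean (447 higher, 542 lower), 274 with at least 4 probesets (156, 118), 596 with the brighter filter (296, 300), 750 with eBayes following the trend (383, 367), 730 with trend and robust (371, 359), 397 at an adjusted p under 0.1 (216, 181) and 489 by 1.5-fold without a test (248, 241), so the excess of rises among the 121 (87, 34) was smaller or gone in these larger sets. It was 0 to 5 with 1 sample left out (1998 to 2519 at an unadjusted p under 0.05), where the lone sample is assumed to vary like the other group. Fewer samples and fewer genes tested are part of some of these settings, and otherwise the cause was not tested. The 8 called lists became 5 with dim probesets left out, 5 with the brighter filter, 0 with an estimated correlation (2 at an unadjusted p under 0.05), 3 with fry and 6 to 9 with 1 sample left out. The 72 genes with unequal change became 91 without a filter, 69 above the upper quartile of probesets, 76 with the brighter filter (41 shared with the 72), 90 after quantile normalization, 263 with the Simes test and 18 to 87 with 1 sample left out. With the replicate number as a block 14 genes, 9 lists and 20 genes with unequal change were called. Arc was not called in that transcript test (diffSplice adjusted p = 0.0911). The labels do not pair samples by number, and deviations of samples with the same number correlated at -0.21 across genes. That sign is the one the crossed pairing would give, but it does not establish a pairing. With the crossed pairing as a block, 61 genes (56 of the 121), 7 lists (6 of the 8) and 115 genes with unequal change (59 of the 72) were called. Splitting the samples by the crossed pairing gave 725 genes at an unadjusted p under 0.05 by limma, against 257 for replicates 1 against replicates 2. Sham replicate 2 and ECS replicate 1 were also the brighter arrays (medians of 6.03 and 6.01, against 5.98 and 5.97). The 725 therefore need not come from a pairing. Which samples belong together, if any, is not known. Of 160 named genes, 39 were past the threshold and 0 of these changed direction in any setting. For many settings this was fixed in advance. Both ECS samples lay beyond both sham samples in each called gene, so leaving out 1 sample could not turn the sign. Blocks and variance models leave the change as it is. Among the other named genes the sign turned for Hes6 (0.032), Ccne2 (-0.14) and Lum (1.5e-05) with dim probesets left out, for Hes6 (0.032), Kif20a (0.12), Cda (-0.17) and Susd5 (0.0048) with the brighter filter, and for Tnf (-0.0069) and Syne1 (-0.21) with the median of probesets. With 1 sample left out, Lmo3 ranged from -0.38 to 0.0084, Mobp from -0.039 to 0.62, Tagln from -0.012 to 0.54 and the oligodendrocyte list from -0.13 to 0.39, and the sign turned without ECS replicate 1 for Lmo3, Mobp and this list and without sham replicate 1 for Tagln. The deposited gene-level table was not run as an alternative because its column names match no label. Dim probesets, near background, limit what can be seen of genes with low signal.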

Other observations

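Several genes that rose encode parts or targets of activin and TGF-beta signalling, and they were picked here because they were called. Besides Inhba, Pmepa1 and Tll1, these are the receptor genes Acvr1c (1.41 ± 0.09 on the log2 scale, SE, adjusted p = 0.0135 by limma) and Acvr1 (0.83 ± 0.09, adjusted p = 0.0395), and the inhibitors of Smad signalling Skil (1.14 ± 0.09, adjusted p = 0.0189) and Smad7 (0.96 ± 0.10, adjusted p = 0.0387). Of 40 other members of the pathway 23 were higher, with a median change of 0.02. The called members had been set apart from these 40, so the values do not tell whether the pathway rose more widely. By limma 3 higher and 4 lower members of the 40 had an unadjusted p under 0.05. They were Tgfb3 (0.68), Ski (0.53) and Smad3 (0.50), and the activin receptor genes Acvr2a (-0.76) and Acvr1b (-0.32), the activin antagonist Fst (-0.58) and Chrd (-0.37), named after their values were seen.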
